A study of Mus musculus with 10 samples.

How the data were processed

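The study measured RNA from sorted mouse prostate cells in 10 libraries of 4 groups. Per the labels' protocols, RNA was extracted from the cells, turned into cDNA with both random and poly(dT) priming in a NuGEN Ovation kit, built into libraries with an Illumina TruSeq DNA kit and sequenced on a HiSeq. The protocol does not say whether the libraries keep the strand of the RNA, or whether the sorted cells had first been cultured, since a culture protocol stands beside it for all libraries. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq 1.8.3 and processed with TopHat and Cufflinks on genome build mm10. The versions of TopHat and Cufflinks are not given in the sources used here. Each library had its own file, per the file headers a Cufflinks tracking table of 63241 transcripts with UCSC identifiers. The values used were FPKM, fragments per kilobase of transcript scaled to the mapped fragments, as computed by the authors and deposited for each transcript. The deposited files also give coverage, the mean depth of bases per transcript, per the file headers. Coverage was not used in any test.

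Groups were taken from the gate named in each label. The labels carry no replicate numbers, so libraries of a group were numbered in the order in which they are listed. Gene names are not in the files. Transcripts were matched by their mm10 coordinates to GENCODE release M21 and to RefSeq genes of GRCm38.p6, the same assembly as mm10. A match needed both ends of a GENCODE transcript or RefSeq gene (2108 by span alone and 9998 by span and spliced length for GENCODE, 9188 for RefSeq), 1 end of a GENCODE transcript (22554), of a RefSeq gene (3910) or of a transcript already named (361), or a span overlap of at least 0.5, intersection over union, with 1 gene (6447). In this way 54566 of 63241 transcripts (86.3%) received a gene symbol. Transcripts shorter than 300 nt (8006) were left out, because fragments are about as long. FPKM was summed over the transcripts of a gene, which gave 24572 genes. A Cufflinks estimate that was not made is recorded in a status column, as failed or, for Sbp, as having too many fragments: this held for 27 transcripts in some library, and 7 genes were left out for it, among them Sbp and Lama2. Of 365 genes in the fixed lists, 357 were in the table. The files list exact zeros for some genes that most cells express, so a gene at 0 is described as listed at 0. There were 473 genes listed at 0 in a library and at 5 FPKM or more in another. Genes with near copies (Sbp and Sbpl, the hemoglobin, Svs, Ly6 and Pate families, MHC class I genes) and overlapping or antisense genes are uncertain, because reads of such genes may be split between them or merged.

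Depth was read from the values. For 4327 isolated transcripts, FPKM multiplied by the effective length fell on steps of 1 fragment, and 92.4% to 94.6% of low values lay within 0.05 of a whole number. The step sizes correspond to 20.3 to 27.2 M (mega) mapped fragments. The steps are whole for isolated transcripts only, so fragment counts were not rebuilt for all genes and no count model was used. At a given transcript length, a gene at 1 FPKM rests on fewer fragments than a gene at a higher value. Values near the filter are taken to carry the widest relative error, which was not measured by level.

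Tests used limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with the pseudocount of 1 fixed in advance. Genes at 1 FPKM or more in at least 2 libraries were tested, 12489 in all. One linear model with a mean for each group was fitted to all 10 libraries (lmFit, contrasts.fit, eBayes with trend, 6 residual degrees of freedom). The groups of 2 and of 3 thus shared an estimate of spread, which takes a gene to vary alike in every group. The Sca-1+ luminal libraries were spread out. Without Sca-1+ luminal replicate 3, calls between basal and Sca-1- luminal libraries rose from 5771 to 6465. A low count of calls in a comparison without that group may therefore reflect its spread. The 4 comparisons were Sca-1+ against Sca-1- luminal, basal against each luminal group, and stromal against the equally weighted mean of the 3 epithelial groups. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Tables and figures were made in Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9.

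Gene lists, the design, the named gene rule and most alternatives were fixed before the data were examined. The 27 lists cover sort markers, basal, luminal, secretory, androgen-responsive, proximal luminal, seminal vesicle, urothelial, fibroblast, smooth muscle, leukocyte, endothelial, erythroid, neuroendocrine, glia and nerve, immediate early, cell cycle, MHC class II, MHC class I and interferon, Notch, Wnt ligand, Wnt response, ER folding and export, oxidative phosphorylation, retinoid, polyamine and basement membrane genes. Each list was tested with camera in limma at a preset inter-gene correlation of 0.01, and again with the correlation estimated from the data, adjusted over 104 list tests. The neuroendocrine list had 2 genes tested and was not given to camera. Named genes are, for each comparison, the 10 with the largest and the 10 with the smallest log2 change among called genes with a mean of at least 5 FPKM in the higher group and no overlap between the libraries of both sides, leaving out predicted and clone names. Chance alone gives 10% of genes no overlap for 3 libraries against 3. Members of the fixed lists were named beside them: the sort markers, called members with a large change, and members that show that a list did not move together. Some genes that the rule names are not reported here.

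The test was checked on simulated data with 12489 genes, of which 200 were changed, 100 per fold size. Of genes changed 4-fold, 83% were recovered for Sca-1+ against Sca-1- luminal, 80% for basal against Sca-1- luminal, 77% for basal against Sca-1+ luminal and 85% for stromal against epithelial libraries. Of genes changed 2-fold, 18%, 4%, 9% and 20% were recovered in the same order, with 4, 2, 4 and 8 false calls. The simulated noise was independent between genes, with the same spread for a gene in every group. In the real comparisons 19.8% to 46.2% of genes were called, so these rates need not hold for the data.

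Alternatives fixed in advance were a pseudocount of 0.1, no filter, a filter of 5 FPKM, median-of-ratios scaling, quantile normalization, a fit of only the groups compared, a robust fit with library weights, a minimum log2 change of 1, and leaving out each library in turn. Chosen after seeing the data were a fit with Sca-1+ luminal replicate 3 as the only library of its gate, stromal against basal and Sca-1- luminal libraries only, inclusion of short transcripts, only transcripts matched at both ends, and removal of genes listed at 0. The genes shared by both comparisons with Sca-1- luminal libraries were set against 20 simulations of unchanged groups.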

Results

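RNA was sequenced from cell populations that had been sorted from the prostates of C57BL/6 mice aged 8 to 12 weeks. The sort used a set of lineage markers (Lin) to remove unwanted cells, and 3 surface proteins: CD24 (gene Cd24a), CD49f (integrin alpha 6, gene Itga6) and Sca-1 (gene Ly6a). The 10 libraries fall into 4 groups. Basal cells, gated as low for CD24 and high for CD49f, gave 2 libraries. Luminal cells, gated as high for CD24 and low for CD49f, gave 3 libraries without Sca-1 and 3 libraries with Sca-1. Stromal cells, negative for CD24 and for CD49f, gave 2 libraries. Values were expression estimates in FPKM per transcript, summed per gene. Depth was 20.3 to 27.2 M (mega) fragments per library, estimated from the steps between low FPKM values. Genes at 1 FPKM or more numbered 9846 to 11346 per library. The labels do not say whether libraries of a group came from separate animals, so every p-value measures the spread between these libraries only. The protocol field shared by all libraries also describes plating and culture of dissociated prostate cells, and it does not say whether the sorted cells had been cultured.

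The libraries separated by gate, except that the Sca-1+ luminal libraries were spread out. Principal component 1 held 52.5% of the variance and component 2 held 24.2%. Correlation of log2(FPKM + 1) between the basal libraries was 0.976, and between the stromal libraries 0.963. Among Sca-1- luminal libraries it was 0.936 to 0.971. Within the Sca-1+ luminal group, replicates 1 and 2 correlated at 0.95, whereas replicate 3 correlated with replicate 2 at 0.911 and with replicate 1 at 0.839. Replicate 3 correlated with Sca-1- luminal replicates 1, 2 and 3 at 0.866, 0.871 and 0.808, and with the basal libraries at 0.846 and 0.852. Replicate 1 of that group correlated with the stromal libraries at 0.915 and 0.916, and replicate 3 did so at 0.703 and 0.735. The 10 most abundant transcripts took 36.3% to 37.4% of the summed FPKM in Sca-1- luminal libraries and 11.2% to 16.3% in the other libraries.

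**Figure D1:**
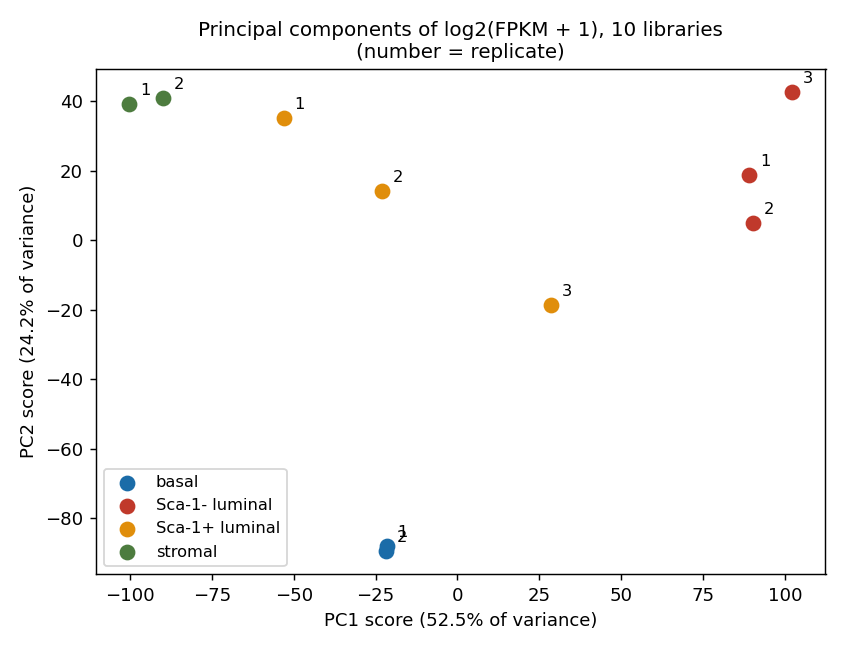
Scores of the 10 libraries on principal components 1 and 2 of log2(FPKM + 1), with the share of variance on each axis, coloured by group and numbered by replicate. Basal, stromal and Sca-1- luminal libraries each lie together, and the 3 Sca-1+ luminal libraries are spread out, from -53.09 on component 1 and 35.08 on component 2 for replicate 1 to 28.63 and -18.63 for replicate 3.

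The markers used in the sort differed between the groups in the order of the gates for most pairs. Ly6a (chromosome 15, 74994877 to 74998031, genome build mm10) stood at 1365 ± 840.5 FPKM (SD, n = 3) in Sca-1+ luminal, 52.3 ± 31.5 (SD, n = 3) in Sca-1- luminal, 447 ± 36.8 (SD, n = 2) in basal and 1610 ± 453 (SD, n = 2) in stromal libraries. Itga6 was highest in basal libraries, at 131 ± 12.6 FPKM (SD, n = 2), and lowest in stromal libraries, at 2.07 ± 1.3 (SD, n = 2). Cd24a was lowest in stromal libraries, at 41.1 ± 22.5 FPKM (SD, n = 2), and reached 197, 412 and 1091 FPKM in Sca-1+ luminal replicates 1, 2 and 3. Basal libraries, gated as low for CD24, held 212 ± 19 FPKM of Cd24a (SD, n = 2), above the value of Sca-1+ luminal replicate 1.

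**Figure D2:**
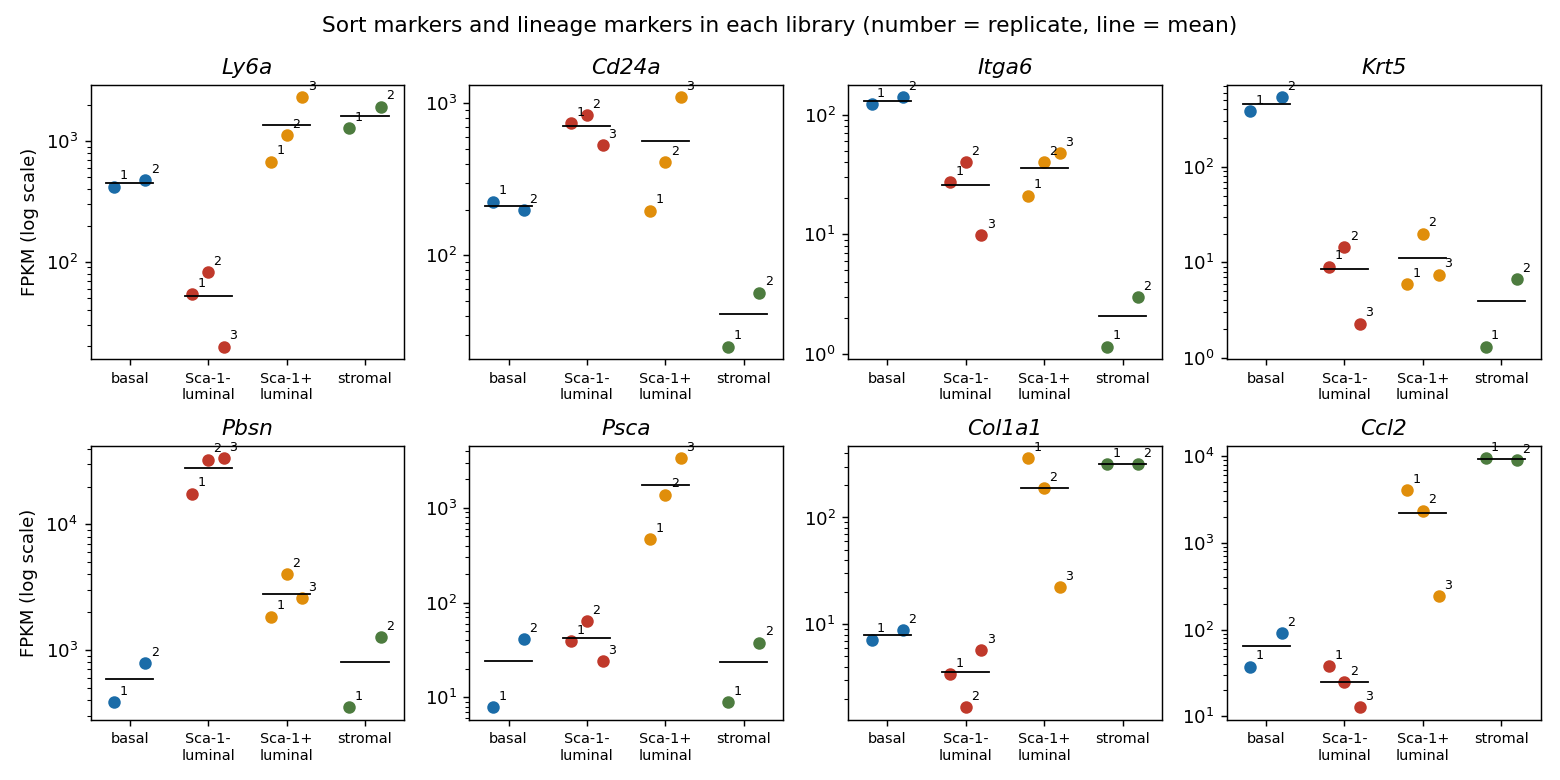
FPKM on a log axis of 3 sort marker genes and 5 lineage marker genes in each library, by group, with the replicate number beside each point and a line at the group mean. Col1a1 stood at 359.7, 189.8 and 22.4 FPKM in Sca-1+ luminal replicates 1, 2 and 3, and at 317 and 314 FPKM in the stromal libraries.

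The comparison of Sca-1+ with Sca-1- luminal libraries asked how luminal cells with and without surface Sca-1 differ. Sca-1+ luminal libraries held more transcripts of proximal luminal markers, genes fixed as a list for the luminal cells near the urethra, and fewer transcripts of prostate secretory proteins. Of the 12 proximal markers 9 were higher, 0 were lower and 3 were not called. Psca (chromosome 15, 74714839 to 74717065), a surface antigen anchored by a lipid, stood at 1736 ± 1477 FPKM (SD, n = 3) against 42.7 ± 20.3 (SD, n = 3). The keratin gene Krt4 stood at 179 ± 175 FPKM (SD, n = 3) against 5.44 ± 2.62 (SD, n = 3), and Ppp1r1b, which encodes a protein phosphatase inhibitor, at 126 ± 67.8 against 9.99 ± 5.59 (SD, n = 3 each). Their log2 changes were 5, 4.45 and 3.52, with limma Benjamini-Hochberg adjusted p of 0.00257 for Psca and 0.00104 for Krt4. Ly6a itself was higher by 4.71 on the log2 scale (SE 0.563, limma Benjamini-Hochberg adjusted p = 0.000633). As a list, the proximal markers had a median log2 change of 3.24 (camera in limma, Benjamini-Hochberg adjusted p = 0.00046), with adjusted p = 0.64 with an estimated correlation. With Sca-1+ luminal replicate 3 alone, 9 of the 12 were again higher.

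Among 14 prostate secretory proteins, 10 were lower in Sca-1+ than in Sca-1- luminal libraries, 1 was higher and 3 were not called. Pbsn (chromosome X, 77837898 to 77853500), which encodes the androgen-regulated secreted protein probasin, fell by 3.33 on the log2 scale, from 28020 ± 9071 FPKM to 2807 ± 1097 (SD, n = 3 each). Tgm4, the prostate transglutaminase, stood at 900 ± 111 FPKM (SD, n = 3) against 5783 ± 927 (SD, n = 3). The member that was higher was Crisp1, which encodes a secreted protein that binds sperm, at 30.3 ± 4.08 FPKM against 7.01 ± 6.28 (SD, n = 3 each). The median log2 change of the list was -2.77 (camera in limma, Benjamini-Hochberg adjusted p = 1.31e-05), with adjusted p = 0.519 with an estimated correlation. Pbsn was not called under quantile normalization. In the fit with replicate 3 as the sole Sca-1+ luminal library, which held the least Col1a1 of its gate, 8 of the 14 were lower and 0 higher, with Crisp1 not called at 2.45 (limma, Benjamini-Hochberg adjusted p = 0.0618).

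Genes of protein folding and export in the endoplasmic reticulum (ER) were lower in Sca-1+ luminal libraries: 17 of 20 were lower, 0 were higher and 3 were not called. Sdf2l1 (chromosome 16, 17130138 to 17132383), which encodes part of an ER chaperone complex, stood at 63 ± 25 FPKM against 358 ± 58.3 (SD, n = 3 each). Sec11c, a subunit of the signal peptidase, stood at 202 ± 35.3 FPKM against 812 ± 83.4 (SD, n = 3 each). Their log2 changes were -2.56 and -2.01. Hspa5, the main ER chaperone, was not called, at a log2 change of -1.25 (limma, Benjamini-Hochberg adjusted p = 0.0572), but was called with median-of-ratios scaling. The median log2 change of the list was -1.69 (camera in limma, Benjamini-Hochberg adjusted p = 1.43e-11), with adjusted p = 0.519 with an estimated correlation. With replicate 3 of the Sca-1+ luminal group alone, 17 of the 20 were lower, where Hspa5 gained its call (-2.02, adjusted p = 0.0169) and Ssr2 lost it (adjusted p = 0.0988). Of 24 oxidative phosphorylation genes 5 were lower and 0 higher, with a median of -0.58 (camera in limma, Benjamini-Hochberg adjusted p = 0.000985), and adjusted p = 0.707 with an estimated correlation. Mitochondrial transcripts took 0.61%, 1.62% and 3.22% of the summed FPKM in Sca-1+ luminal replicates 1, 2 and 3, 3.69% to 5.11% in Sca-1- luminal, 1.06% and 1.44% in basal and 1.39% and 1.43% in stromal libraries. The count of lower oxidative phosphorylation genes was 12 without Sca-1+ luminal replicate 3, 2 to 3 without any other luminal library or without either basal library, and 1 with Sca-1+ luminal replicate 3 alone, where camera did not call the list (adjusted p = 0.323).

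Fibroblast genes were also higher in Sca-1+ luminal libraries. All 18 tested members were called higher, and 16 to 18 were with any library left out. Col1a1 (chromosome 11, 94936270 to 94951856), a fibrillar collagen gene, stood at 191 ± 169 FPKM (SD, n = 3) against 3.59 ± 2.02 (SD, n = 3). Serpinf1, which encodes a secreted serpin, was at 398, 210 and 28.4 FPKM in Sca-1+ luminal replicates 1, 2 and 3, against 395 and 432 FPKM in the stromal libraries. The 10 genes with the largest log2 increase under the fixed rule were Gfpt2, Ccl2, Serpinf1, Pltp, Ccl7, Mfap4, Penk, Tcf21, Ugdh and Ptgs2. All 10 had a higher mean in stromal than in Sca-1+ luminal libraries, such as Gfpt2 at 1828 against 626 FPKM and Penk at 4181 against 1264 FPKM. Ccl2, a chemokine gene, stood at 4052, 2356 and 245 FPKM in Sca-1+ luminal replicates 1, 2 and 3, at 25.3 ± 12.6 FPKM (SD, n = 3) in Sca-1- luminal libraries and at 9280 ± 278 (SD, n = 2) in stromal libraries. Pltp was listed at 0 in every Sca-1- luminal library and at 99.5, 78 and 14.3 FPKM in Sca-1+ luminal replicates 1, 2 and 3. The median log2 change of the fibroblast list was 4.35 (camera in limma, Benjamini-Hochberg adjusted p = 3.51e-07), with adjusted p = 0.564 with an estimated correlation. With replicate 3 as the sole Sca-1+ luminal library, 12 of the 18 were higher, at a median of 2.21.

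Members of 3 further lists were higher in this comparison, in which Col1a1 differed between the Sca-1+ luminal libraries as given. Of 18 Wnt ligands and antagonists 13 were higher and 0 lower, among them Wif1, a secreted Wnt inhibitor, with a log2 change of 4.25, and Wnt11 with 3.55 (camera in limma, Benjamini-Hochberg adjusted p = 5.28e-05 for the list), with adjusted p = 0.534 with an estimated correlation. With Sca-1+ luminal replicate 3 alone, 5 of the 18 were higher, among them Wnt7b at 3.06 and Wnt4 at 2.63, while Wif1 stood at 2.38 and Wnt11, not called, at 1.1. In the fit of all libraries Wnt7b and Wnt4 stood at 1.69 and 1.64, calls that were lost under quantile normalization, for Wnt7b also without Sca-1- luminal replicate 2 or 3, and for Wnt4 without either basal library, Sca-1- luminal replicate 1 or 2, or Sca-1+ luminal replicate 2 or 3. Of 10 basement membrane genes 9 were higher, such as Nid1 at 4 and Col4a1 at 3.07 on the log2 scale (camera in limma, Benjamini-Hochberg adjusted p = 0.00109 for the list), with adjusted p = 0.537 with an estimated correlation, and 5 were higher with replicate 3 alone. Of 20 genes of MHC class I presentation and interferon response 12 were higher, including the interferon-induced gene Ifit3 at 2.85 (camera in limma, Benjamini-Hochberg adjusted p = 0.00175 for the list), with adjusted p = 0.651 with an estimated correlation, and 3 were higher with replicate 3 alone, where neither the list (adjusted p = 0.0927) nor Ifit3 was called, the gene at 1.6.

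Retinoid metabolism genes went both ways between the luminal gates, with 8 of 13 higher and 1 lower. Aldh1a3, an enzyme that makes retinoic acid, stood at 125 ± 52 FPKM against 5.26 ± 4.58 (SD, n = 3 each), and Rdh10, a retinol dehydrogenase, at 70.7 ± 2.51 against 4.69 ± 2.05 (SD, n = 3 each). Crabp1, which binds retinoic acid in the cytoplasm, was the member that was lower, at 6.17 ± 5.11 FPKM against 60.2 ± 23.4 (SD, n = 3 each). The list had a median log2 change of 1.48 (camera in limma, Benjamini-Hochberg adjusted p = 0.00778), with adjusted p = 0.534 with an estimated correlation. Among the Sca-1+ luminal libraries Col1a1 differed as stated, and with replicate 3 alone 4 were higher and 1 lower (list not called, adjusted p = 0.0531), with Aldh1a3 at 4.98, Rdh10 at 3.75 and Crabp1 at -5.51 on the log2 scale. Of 15 basal genes 6 were higher, with a median of 0.87 (camera in limma, Benjamini-Hochberg adjusted p = 0.0368), and adjusted p = 0.651 with an estimated correlation. That count was 3 without Sca-1- luminal replicate 3, and the list was not called with Sca-1+ luminal replicate 3 alone (adjusted p = 0.0741). Krt15, a keratin gene of that list, stood at 1577 ± 1439 FPKM against 64.2 ± 36.7 (SD, n = 3 each), whereas Krt5 was not called at 11.1 ± 7.71 against 8.58 ± 6.09 (SD, n = 3 each). The log2 change of Krt5 was 0.42, and it was -0.22 without Sca-1- luminal replicate 3 and -0.06 without Sca-1+ luminal replicate 2.

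The 10 genes with the largest log2 decrease in Sca-1+ luminal libraries were Sbpl, Spink1, Smim27, Wfdc3, Msmb, Nme3, Yipf2, Ang, Defb50 and Tmx2. Spink1, a secreted protease inhibitor gene, stood at 7848, 13620 and 7.96 FPKM in Sca-1+ luminal replicates 1, 2 and 3 and at 111800 ± 24080 (SD, n = 3) in Sca-1- luminal libraries, and its call was lost in 7 of 12 settings, among them without each of the 3 Sca-1- luminal, 2 basal and 2 stromal libraries, and also under quantile normalization. Sbpl stood at 361, 475 and 0.66 FPKM against 9546 ± 573 (SD, n = 3). Smim27 was listed at 0 in all 3 Sca-1+ luminal libraries and at 66.6, 66.9 and 89 FPKM in the Sca-1- luminal libraries. Tmx2 was listed at 0 in all 3 Sca-1+ luminal libraries and at 20.8, 10.6 and 15.9 FPKM in Sca-1- luminal libraries. Nme3, Yipf2 and Ang were listed at 0 in Sca-1+ luminal replicates 1 and 2, and at 64.8, 8.51 and 18.7 FPKM in replicate 3. In Sca-1- luminal replicates 1, 2 and 3, Nme3 stood at 85.2, 86.1 and 99.9 FPKM, Yipf2 at 41, 36.6 and 59.3, and Ang at 44.1, 61.9 and 56.4. The call of Nme3 was lost without any single luminal library except Sca-1+ luminal replicate 3, and that of Ang without Sca-1- luminal replicate 3 or Sca-1+ luminal replicate 2. Wfdc3 was not called without Sca-1- luminal replicate 3, and Nme3, Ang and Tmx2 were not with Sca-1+ luminal replicate 3 alone.

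In total 4404 of 12489 genes tested, or 35.3%, were called between the luminal gates, 2733 higher and 1671 lower in Sca-1+ luminal libraries (limma, Benjamini-Hochberg adjusted p under 0.05). The share higher was 62.1%, and it was 48.8% with median-of-ratios scaling and 40.4% with quantile normalization, which moved the median log2 change of all genes by -0.14 and -0.26. The count was 2743 without Sca-1- luminal replicate 3, 2764 without Sca-1+ luminal replicate 2 and 2068 with Sca-1+ luminal replicate 3 alone, of which 1807 were among the 4404.

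Comparing basal with Sca-1- luminal libraries addressed how the basal lineage differs from the main secretory lineage. All 15 tested basal genes were higher in basal libraries. Krt5 (chromosome 15, 101707070 to 101712891), a keratin gene of basal cells, stood at 459 ± 108 FPKM (SD, n = 2) against 8.58 ± 6.09 (SD, n = 3), a log2 change of 5.83 (SE 0.725, limma Benjamini-Hochberg adjusted p = 0.000229). Col17a1, a hemidesmosome collagen gene, stood at 159 ± 2.9 FPKM (SD, n = 2) against 2.46 ± 1.87 (SD, n = 3), and Trp63, the gene of the basal transcription factor p63, at 24.4 ± 23.1 (SD, n = 2) against 0.253 ± 0.318 (SD, n = 3). The list had a median log2 change of 4.41 (camera in limma, Benjamini-Hochberg adjusted p = 2.34e-09), with adjusted p = 0.519 with an estimated correlation. Other genes with the largest increase were Krt17, Krt14, Aqp3, Egln3, Slco4a1, F3 and Col18a1, and Pltp, which was listed at 0 in the Sca-1- luminal libraries, stood at 108 and 87.1 FPKM in basal libraries. F3, tissue factor, reached 2228 ± 80.5 FPKM (SD, n = 2) in basal libraries.

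Secretory genes were lower in basal libraries, with 13 of 14 called. Pbsn stood at 587 ± 283 FPKM (SD, n = 2) against 28020 ± 9071 (SD, n = 3) and fell by 5.61 on the log2 scale (camera in limma for the list, Benjamini-Hochberg adjusted p = 6.36e-06), with adjusted p = 0.519 with an estimated correlation. Of 20 ER folding and export genes 18 were lower, with Sec11c at a log2 change of -4.31 and Sdf2l1 at -3.98 (camera in limma, Benjamini-Hochberg adjusted p = 1.77e-08), with adjusted p = 0.519 with an estimated correlation. Seminal vesicle secretory genes were lower for 5 of 7 (camera in limma, Benjamini-Hochberg adjusted p = 0.011), with adjusted p = 0.651 with an estimated correlation. Svs4 stood at 7.8 ± 2.72 FPKM (SD, n = 2) in basal libraries, and at 2467, 327 and 10740 FPKM in Sca-1- luminal replicates 1, 2 and 3. Of 16 luminal genes 8 were lower and 0 higher, such as Tspan1, a tetraspanin gene, at a log2 change of -5 (camera in limma, Benjamini-Hochberg adjusted p = 0.011), with adjusted p = 0.534 with an estimated correlation. The luminal keratin genes Krt8 and Krt18 were not called, at log2 changes of 0.22 and -0.08. Krt8 stood at -0.29 without basal replicate 2 and -0.54 without Sca-1- luminal replicate 3. Krt18 stood at 0.11 without basal replicate 1 and 0.44 without Sca-1- luminal replicate 2, and had the opposite sign under quantile normalization. Androgen-responsive genes went both ways, with 11 of 20 lower and 2 higher (camera in limma, Benjamini-Hochberg adjusted p = 0.022), and adjusted p = 0.534 with an estimated correlation. That count of lower genes was 7 without basal replicate 2.

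Notch pathway genes were higher in basal libraries for 6 of 11 and lower for 0, led by ligand genes. Dll1 stood at 43.2 ± 14.5 FPKM (SD, n = 2) against 0.827 ± 0.485 (SD, n = 3), Jag1 at 45.2 ± 0.496 (SD, n = 2) against 1.81 ± 0.361 (SD, n = 3), and Jag2 at 28.1 ± 14.4 (SD, n = 2) against 0.858 ± 0.469 (SD, n = 3). The list had a median log2 change of 0.79 (camera in limma, Benjamini-Hochberg adjusted p = 0.00888), with adjusted p = 0.534 with an estimated correlation. Basement membrane genes were higher for 5 of 10, with Col4a1 at a log2 change of 3.85 and Hspg2, perlecan, at 3.12 (camera in limma, Benjamini-Hochberg adjusted p = 0.00778), with adjusted p = 0.649 with an estimated correlation. Oxidative phosphorylation genes, beside the mitochondrial shares given above, were lower for 10 of 24 (camera in limma, Benjamini-Hochberg adjusted p = 0.0107), with adjusted p = 0.766 with an estimated correlation, and for 4 without basal replicate 1 and 5 without basal replicate 2. All 5 tested erythroid genes were lower (camera in limma, Benjamini-Hochberg adjusted p = 0.0242), with adjusted p = 0.651 with an estimated correlation, and 1 was without basal replicate 1.

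The 10 genes with the largest decrease in basal libraries were Elob, Svs4, Sbpl, Svs5, Spinkl, Nme3, H2-Ke6, Smim27, Svs2 and Pate9. Elob, Nme3, H2-Ke6 and Smim27 were listed at 0 in both basal libraries. The calls of Elob and Sbpl were lost without either basal library, and that of Elob also without any Sca-1- luminal library. Pate9 stood at 3.04 ± 0.422 FPKM (SD, n = 2) against 226 ± 76.3 (SD, n = 3). Cd24a was lower in basal libraries, by a log2 change of -1.7 (limma, Benjamini-Hochberg adjusted p = 0.0495), a call that was lost in 9 of 12 settings, among them without either basal library or any Sca-1- luminal library. In all, 5771 genes were called, 46.2% of those tested, with 2524 higher and 3247 lower. The count was 3803 without basal replicate 1 and 3808 without basal replicate 2, where the remaining basal library is taken to vary like the other groups.

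The comparison of basal with Sca-1+ luminal libraries asked what separates the populations that both held Ly6a well above the Sca-1- luminal level. Ly6a was not called between them, at a log2 change of -1.43 (limma, Benjamini-Hochberg adjusted p = 0.135). Basal genes were higher in basal libraries for 12 of 15, with Krt5 at 5.41 and Col17a1 at 5.2 on the log2 scale, and 3 were not called (camera in limma, Benjamini-Hochberg adjusted p = 7.04e-16), with adjusted p = 0.519 with an estimated correlation. Krt15 was among those not called, at 0.96, and stood at -0.47 with Sca-1+ luminal replicate 3 alone. The genes with the largest increase were Lgals7, Krt14, Krt5, Krt17, Slco4a1, Col17a1, Cldn1, Krt75, Sult5a1 and Cdh3. Lgals7, a galectin gene of stratified epithelia, stood at 226 ± 86.1 FPKM (SD, n = 2) against 4.28 ± 4.2 (SD, n = 3). Notch ligand genes were again higher, with Dll1 at 3.96, Jag2 at 3.67 and Jag1 at 2.74 on the log2 scale, and 4 of 11 members of the pathway called (camera in limma, Benjamini-Hochberg adjusted p = 0.0133), with adjusted p = 0.537 with an estimated correlation. Krt14 and Krt17 were not called without either basal library, nor Cldn1 without basal replicate 2.

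Lower in basal than in Sca-1+ luminal libraries were Psca, Svs2, Svs5, Tff3, Pate4, Ppp1r1b, Krt4, Nupr1, Gsdmc3 and Cd52. Psca fell by 6.07 on the log2 scale, from 1736 ± 1477 FPKM (SD, n = 3) to 24.4 ± 23.4 (SD, n = 2). Nupr1, a stress-response gene, stood at 54.4 ± 41.8 FPKM (SD, n = 2) against 1694 ± 780 (SD, n = 3). Tff3, a mucosal trefoil peptide gene, was listed at 0 in both basal libraries and had a mean of 51.5 FPKM in Sca-1+ luminal libraries. Luminal genes were lower for 9 of 16, with Tspan1 at -4.16 and Cldn3, a tight junction gene, at -4.09 on the log2 scale (camera in limma, Benjamini-Hochberg adjusted p = 0.00771), with adjusted p = 0.534 with an estimated correlation. Secretory genes were lower for 8 of 14 (camera in limma, Benjamini-Hochberg adjusted p = 0.00615), with adjusted p = 0.534 with an estimated correlation. Urothelial genes were lower for 6 of 10 (camera in limma, Benjamini-Hochberg adjusted p = 0.00523), with adjusted p = 0.528 with an estimated correlation. The luminal count was 5 without basal replicate 1 and 4 without basal replicate 2, the secretory count 5 and 4. The secretory list was not called with Sca-1+ luminal replicate 3 alone (adjusted p = 0.513). Svs2, Svs5 and Pate4 were not called without either basal library or with Sca-1+ luminal replicate 3 alone, and Cldn3 was not without basal replicate 1.

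Fibroblast genes were lower in basal libraries than in Sca-1+ luminal libraries for 13 of 18 (camera in limma, Benjamini-Hochberg adjusted p = 6.86e-05), with adjusted p = 0.651 with an estimated correlation. Col1a1 stood at 360, 190 and 22.4 FPKM in Sca-1+ luminal replicates 1, 2 and 3, and 7.17 and 8.77 FPKM in basal libraries. The fibroblast count was 1 without either basal library and 4 without Sca-1+ luminal replicate 2. Interferon and MHC class I genes were lower for 13 of 20 (camera in limma, Benjamini-Hochberg adjusted p = 0.000175), with adjusted p = 0.64 with an estimated correlation, and the count was 0 without basal replicate 1, 1 without basal replicate 2 and 6 without Sca-1+ luminal replicate 2. Wnt ligands and antagonists were lower for 5 of 18 (camera in limma, Benjamini-Hochberg adjusted p = 0.0137), with adjusted p = 0.651 with an estimated correlation. Their count was 2 without either basal library or Sca-1+ luminal replicate 2, 3 without Sca-1- luminal replicate 1 and 11 without Sca-1+ luminal replicate 3. ER folding and export genes were lower for 5 of 20 (camera in limma, Benjamini-Hochberg adjusted p = 0.0131), with adjusted p = 0.651 with an estimated correlation, and the count was 1 without either basal library, 3 without Sca-1+ luminal replicate 2 and 11 without Sca-1+ luminal replicate 3. Camera did not call the interferon, Wnt ligand and ER lists with Sca-1+ luminal replicate 3 alone (adjusted p = 0.0536, 0.486 and 0.183).

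Between basal and Sca-1+ luminal libraries 2475 genes were called, 19.8% of those tested, with 548 higher and 1927 lower in basal libraries. The share higher was 22.1%, and it was 35.8% with median-of-ratios scaling and 53.3% with quantile normalization, which moved the median log2 change of all genes by 0.15 and 0.37. The count was 848 without basal replicate 1, 648 without basal replicate 2, 1491 without Sca-1+ luminal replicate 2 and 1268 in a fit of these 5 libraries alone.

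Many genes were called in the same direction in basal and in Sca-1+ luminal libraries, each against the Sca-1- luminal libraries: 1486 were higher in both and 1536 lower in both, with 33 in opposite directions. Ly6a and Krt15 were higher in both, and Pbsn, Tgm4, Sec11c and Sdf2l1 lower in both. Independent lists of the same sizes would share 552 and 434. The comparisons share their Sca-1- luminal libraries, and the covariance of their log2 changes was 1.16, against 0.062 in 20 simulations of unchanged groups, a difference of 1.09. Across genes, which are not independent replicates, Pearson's r was 0.723 against 0.443 in the simulations, where 0 genes on average were called in both. Every simulated group had the same mean, so the lack of shared calls there was set in advance. A gene that differs in the Sca-1- luminal libraries alone can be called in both comparisons. The shared count therefore does not show that basal and Sca-1+ luminal libraries resemble each other. The 3 shared libraries cannot be split into parts of 2, so part of the excess may come from them. The share higher was 49.2%, and it was 37.9% with median-of-ratios scaling and 34% with quantile normalization. Without Sca-1- luminal replicate 3 the shared genes numbered 1857, without Sca-1+ luminal replicate 2 they numbered 2009, and with Sca-1+ luminal replicate 3 alone 1520.

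Stromal libraries were compared with the equally weighted mean of the 3 epithelial groups, to find the genes of the stromal gate. All 18 fibroblast genes were higher, and 15 were without either stromal library. Dpt, an extracellular matrix gene, stood at 249 ± 97 FPKM (SD, n = 2) and Lum, a proteoglycan gene, had a log2 change of 5.33 (camera in limma for the list, Benjamini-Hochberg adjusted p = 2.82e-11), with adjusted p = 0.534 with an estimated correlation. Col1a1 stood at 315 ± 1.93 FPKM (SD, n = 2). The 10 genes with the largest increase were Ccl7, Ccl2, Sult1e1, Ptx3, Thbd, Dpt, Penk, Cxcl13, Clec3b and Mfap5. The chemokine genes Ccl7 and Ccl2 reached 6145 ± 738 and 9280 ± 278 FPKM (SD, n = 2 each), with log2 changes of 6.27 and 6.22. Smooth muscle genes were called higher for 2 of 11, calls that needed both stromal libraries, and Acta2, smooth muscle actin, stood at 60.3 ± 22.2 FPKM (SD, n = 2). The epithelial mean includes the Sca-1+ luminal group. Without replicate 3 of that group, 10 of 11 smooth muscle genes were higher in it than in Sca-1- luminal libraries. The low count therefore does not show a lack of smooth muscle transcripts in the stromal gate.

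Epithelial genes were lower in stromal libraries. Among the 10 with the largest decrease were Cdh1, Sprr1a, Krt8, Urah, Cbr2, Epcam, Krt18, Cldn7 and Cldn4. Cdh1, the gene of the epithelial adhesion protein E-cadherin (chromosome 8, 106603368 to 106670246), stood at 12.1 ± 10.5 FPKM (SD, n = 2) in stromal libraries, and at 711 ± 66.6 (SD, n = 2) in basal, 147 ± 90.6 (SD, n = 3) in Sca-1- luminal and 408 ± 183 (SD, n = 3) in Sca-1+ luminal libraries. Of 15 basal genes 14 were lower and 1, Egfr, was higher (camera in limma, Benjamini-Hochberg adjusted p = 1.31e-05), with adjusted p = 0.528 with an estimated correlation. Of 16 luminal genes 12 were lower and 1 was higher (camera in limma, Benjamini-Hochberg adjusted p = 0.000175), with adjusted p = 0.519 with an estimated correlation. All 12 proximal luminal markers were lower (camera in limma, Benjamini-Hochberg adjusted p = 3.15e-05), with adjusted p = 0.537 with an estimated correlation. Without stromal replicate 1, where 1 stromal library is taken to vary like the other groups, 6 basal genes and 1 proximal marker were lower, and Sprr1a, Krt8, Urah and Cldn4 were not called. Without stromal replicate 2, 9 basal genes and 9 proximal markers were lower. Egfr lost its call in 7 of 12 settings, and also under quantile normalization.

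In stromal libraries 3 further lists had most members higher. Wnt ligands and antagonists were higher for 13 of 18 and lower for 1, with Wif1 at 4.26 and Sfrp2, a secreted Wnt antagonist, at 3.95 on the log2 scale, and the epithelial ligand gene Wnt7b at -3.15 (camera in limma, Benjamini-Hochberg adjusted p = 3.99e-06 for the list), with adjusted p = 0.534 with an estimated correlation. Interferon and MHC class I genes were higher for 15 of 20, with Gbp2 at 3.18 and Isg15 at 3.16 (camera in limma, Benjamini-Hochberg adjusted p = 2.96e-07), with adjusted p = 0.534 with an estimated correlation. Basement membrane genes were higher for 9 of 10 and lower for 1, Lama5, at -3.13 (camera in limma, Benjamini-Hochberg adjusted p = 0.000929), with adjusted p = 0.537 with an estimated correlation. Retinoid metabolism genes were higher for 6 of 13 and lower for 1, with Rdh10 at 2.6 (camera in limma, Benjamini-Hochberg adjusted p = 0.0136), with adjusted p = 0.534 with an estimated correlation. Without stromal replicate 1 or 2, the Wnt count was 8 higher, and the basement membrane count was 1 or 3. The interferon count was 3 without stromal replicate 2, where neither Gbp2 nor Isg15 was called. Lama5 was not called without stromal replicate 1.

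In the stromal comparison 4280 genes were called, 34.3% of those tested, 1972 higher and 2308 lower. The count was 1468 without stromal replicate 1 and 1906 without stromal replicate 2. Median-of-ratios scaling moved the median log2 change of all genes by 0.11. The share higher was 46.1%, and it was 52.4% with median-of-ratios scaling and 51.2% at a minimum log2 change of 1, so that the larger side changed.

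The remaining lists follow by count, with brackets for the range of some counts over the fits that leave out 1 library. A count without brackets could vary too, such as 4 lower androgen-responsive genes between the luminal gates without Sca-1- luminal replicate 3. Between the luminal gates, limma called 4 of 16 luminal genes lower (2 to 5) and 2 higher, 6 of 20 androgen-responsive genes lower and 3 higher (1 to 4), and 3 of 10 urothelial (3 to 5), 3 of 11 smooth muscle (0 to 10), 4 of 11 Notch pathway (1 to 6), 5 of 12 cell cycle and 3 of 15 immediate early genes higher. Of 7 seminal vesicle genes 1 was lower, but 7 were without Sca-1- luminal replicate 2, and 0 were without either basal library, another Sca-1- luminal library or Sca-1+ luminal replicate 1 or 2. Wnt response genes went both ways, with 2 of 12 higher (0 to 4) and 1 lower (1 to 2), and 1 of 10 polyamine genes (1 to 2) and 1 of 2 neuroendocrine genes (0 to 1) were higher. Leukocyte, endothelial, erythroid and MHC class II genes had 0 called. Without Sca-1+ luminal replicate 3, the library with the least Col1a1 of its gate, 7 of 11 endothelial and 10 of 11 smooth muscle genes were higher, and without replicate 1 or 2 the smooth muscle count was 0. With Sca-1+ luminal replicate 3 alone, camera called the endothelial and smooth muscle lists down (adjusted p = 0.0149 and 0.0305) and the urothelial list up (adjusted p = 0.019), with 5 of 10 urothelial genes higher. Glia and nerve genes were lower for 4 of 6 (2 to 4; camera in limma, Benjamini-Hochberg adjusted p = 0.0489), with adjusted p = 0.537 with an estimated correlation, and the list was not called with median-of-ratios scaling.

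Against Sca-1- luminal libraries, basal libraries were called higher for 4 of 12 proximal luminal markers (2 to 4) and lower for 1 (0 to 1), higher for 6 of 13 retinoid genes (2 to 7) and lower for 1, and higher for 5 of 12 cell cycle genes (3 to 5) and lower for 1 (0 to 2). Higher were 1 of 18 fibroblast (0 to 7), 2 of 11 smooth muscle, 2 of 6 glia and nerve (0 to 2), 3 of 18 Wnt ligand (0 to 6) and 3 of 10 polyamine genes. The fibroblast count was 7 without Sca-1+ luminal replicate 3 and 0 without any basal or Sca-1- luminal library, and the glia count was 0 without basal replicate 1. Lower were 3 of 10 urothelial, 1 of 10 leukocyte (1 to 2), 1 of 11 endothelial (0 to 1), 2 of 2 neuroendocrine (0 to 2) and 3 of 20 interferon and MHC class I genes. Immediate early genes had 2 higher (1 to 3) and 2 lower (0 to 4), Wnt response genes 2 higher (0 to 2) and 2 lower (1 to 2), and MHC class II genes 0 called. Against Sca-1+ luminal libraries, basal libraries were called lower for 7 of 20 androgen-responsive (3 to 7), 5 of 12 proximal luminal (3 to 6), 4 of 7 seminal vesicle (0 to 5), 1 of 10 leukocyte (1 to 2), 2 of 5 erythroid (0 to 5) and 1 of 2 neuroendocrine genes (1 to 2). Lower too were 3 of 15 immediate early (0 to 3), 1 of 7 MHC class II (0 to 1), 3 of 13 retinoid (0 to 5), 1 of 24 oxidative phosphorylation (0 to 4) and 1 of 10 basement membrane genes (0 to 5). Smooth muscle genes were higher for 2 of 11 (0 to 2), Wnt response genes had 1 higher (0 to 1) and 1 lower (0 to 3), and endothelial and cell cycle genes had 0 called. Without Sca-1+ luminal replicate 3, 8 of 11 endothelial, 5 of 11 smooth muscle and 5 of 10 basement membrane genes were lower in basal libraries, whereas with that library alone camera called these lists up (adjusted p = 0.0476, 4.58e-07 and 0.00215). The seminal vesicle count was 0 without either basal library. Glia and nerve genes were higher for 2 of 6 (1 to 4; camera in limma, Benjamini-Hochberg adjusted p = 0.000175), with adjusted p = 0.519 with an estimated correlation, and polyamine genes for 2 of 10 (1 to 2; camera in limma, Benjamini-Hochberg adjusted p = 0.0368), with adjusted p = 0.519 with an estimated correlation. The polyamine list was not called with Sca-1+ luminal replicate 3 alone (adjusted p = 0.0689), whereas the proximal luminal and oxidative phosphorylation lists were called down there (adjusted p = 0.000703 and 0.00764).

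In stromal libraries, secretory genes were lower for 9 of 14 (camera in limma, Benjamini-Hochberg adjusted p = 0.000729), with adjusted p = 0.534 with an estimated correlation, and for 4 without stromal replicate 1 and 5 without stromal replicate 2. Lower were also 5 of 10 urothelial genes (4 to 8; camera in limma, Benjamini-Hochberg adjusted p = 0.00651), with adjusted p = 0.528 with an estimated correlation, and 7 of 20 ER genes (camera in limma, Benjamini-Hochberg adjusted p = 0.016), with adjusted p = 0.651 with an estimated correlation. So were, beside the mitochondrial shares given, 4 of 24 oxidative phosphorylation genes (camera in limma, Benjamini-Hochberg adjusted p = 0.00771), with adjusted p = 0.745 with an estimated correlation, and 4 of 5 erythroid genes (camera in limma, Benjamini-Hochberg adjusted p = 0.0472), with adjusted p = 0.666 with an estimated correlation. The erythroid count was 1 without Sca-1+ luminal replicate 2. Glia and nerve genes were lower for 3 of 6 (camera in limma, Benjamini-Hochberg adjusted p = 0.0329), with adjusted p = 0.537 with an estimated correlation. Androgen-responsive genes were lower for 7 of 20 and higher for 2 (camera in limma, Benjamini-Hochberg adjusted p = 0.0497), with adjusted p = 0.545 with an estimated correlation. The ER, oxidative phosphorylation and erythroid counts were 0 without stromal replicate 1, the glia count was 1 without either stromal library, and the count of lower androgen-responsive genes was 4 without stromal replicate 1, that of higher ones 0 without either stromal library. Without stromal replicate 2 the erythroid count was 0 and the oxidative phosphorylation count 2, and the latter was 11 without Sca-1+ luminal replicate 1. With Sca-1+ luminal replicate 3 alone, camera did not call the androgen-responsive, erythroid, glia and ER lists (adjusted p = 0.13, 0.139, 0.0984 and 0.0608). Of the other lists, 4 of 7 seminal vesicle (0 without either stromal library) and 1 of 10 leukocyte genes were lower and 1 of 11 endothelial genes was higher (0 to 1). Neuroendocrine genes had 1 higher and 1 lower (0 to 1 each), immediate early genes 1 (0 to 3) and 3 (0 to 4), and cell cycle genes 2 (1 to 2) and 1 (0 to 1). Notch genes had 2 higher (0 to 3) and 3 lower (1 to 3), Wnt response genes 4 (1 to 5) and 2 (0 to 3), polyamine genes 2 (1 to 2) and 3 (0 to 3), and MHC class II genes 0 called.

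Adjusted over the list alone, the counts were the same as over all genes except in the following lists. Between the luminal gates, higher counts became 7 for basal, 4 for androgen-responsive, 2 for immediate early, 13 for interferon, 6 for Notch and 14 for Wnt ligand genes, and lower counts 12 for secretory, 0 for seminal vesicle, 18 for ER and 2 for oxidative phosphorylation genes. For basal against Sca-1- luminal libraries, adjusted over the list alone, lower counts became 14 for secretory, 13 for androgen-responsive, 7 for seminal vesicle, 0 for endothelial, 1 for Notch and 20 for ER genes, and higher counts 0 for fibroblast, 0 for Wnt ligand and 1 for Wnt response genes. For basal against Sca-1+ luminal libraries, adjusted over the list alone, higher counts became 14 for basal, 4 for glia and 1 for immediate early genes. Lower counts there became 10 for luminal, 10 for secretory, 6 for proximal, 16 for fibroblast, 5 for erythroid, 2 for neuroendocrine, 15 for interferon, 1 for Notch, 6 for Wnt ligand, 10 for ER and 0 for oxidative phosphorylation genes. For stromal libraries, adjusted over the list alone, lower counts became 6 for urothelial, 5 for erythroid, 5 for glia, 2 for immediate early and 0 for oxidative phosphorylation genes, and higher counts 0 for endothelial, 17 for interferon, 15 for Wnt ligand and 5 for Wnt response genes.

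Of 104 list tests, camera in limma called 47 at the preset correlation, 19 up and 28 down, and 53 had an unadjusted p under 0.05. With an estimated correlation it called 0, and 9 had an unadjusted p under 0.05. It called 46 with Sca-1+ luminal replicate 3 alone, of which 34 were among the 47. The estimated correlations ran from -0.055 for polyamine to 0.908 for erythroid genes, and only that of polyamine genes lay below the preset 0.01. With them camera did not call even the basal list in basal against Sca-1- luminal libraries, where all 15 genes were higher. A lack of calls in that setting therefore does not show that a list was unchanged, and the preset value understates the correlation of most lists. The median of no called list changed sign under median-of-ratios scaling or quantile normalization. Between the luminal gates the medians of leukocyte, cell cycle, Wnt response and polyamine genes, none of them called, changed sign under quantile normalization or both scalings, as did those of endothelial, cell cycle and interferon genes in basal against Sca-1- luminal libraries. In basal against Sca-1+ luminal libraries the medians of smooth muscle, immediate early, cell cycle, Wnt response and basement membrane genes changed sign under a scaling, and in stromal libraries those of endothelial and Notch genes. Median and camera direction differed for leukocyte and Wnt response genes between the luminal gates, and for immediate early and cell cycle genes in basal against Sca-1- luminal libraries, where the median was negative and the mean positive. In basal against Sca-1+ luminal libraries they differed for sort marker, smooth muscle, immediate early, cell cycle, Wnt response and basement membrane genes, and in stromal libraries for endothelial and Notch genes. Median and mean differed in sign for Wnt response genes in basal against Sca-1- luminal libraries and for endothelial and cell cycle genes in stromal libraries. Log2 changes are on the log2(FPKM + 1) scale, which understates the change of genes at low FPKM.

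**Figure D3:**
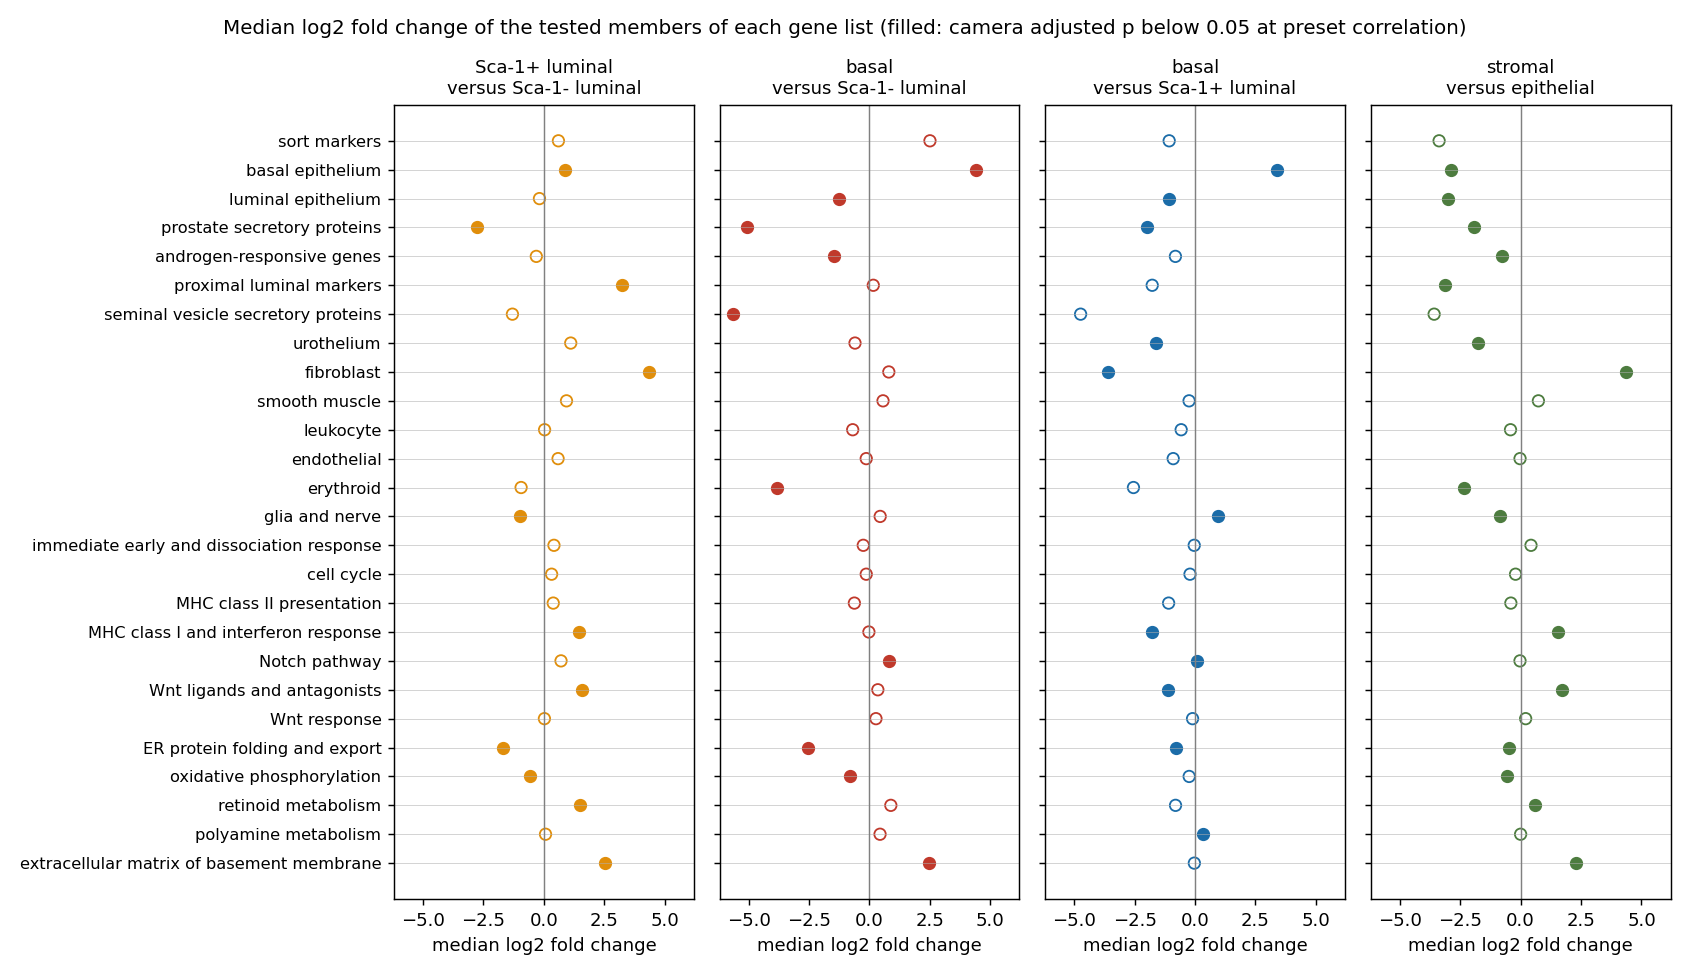
Median log2 change of the tested members of each fixed gene list, on the log2(FPKM + 1) scale, in the 4 comparisons, filled where the Benjamini-Hochberg adjusted p of camera in limma was under 0.05 at the preset correlation. The fibroblast list stands at 4.35 in Sca-1+ against Sca-1- luminal libraries and at 4.35 in stromal against epithelial libraries. These values have different baselines, since the epithelial mean includes the Sca-1+ luminal group, so they do not show equal fibroblast levels in both gates. The ER list stands at -1.69 and -2.52 in Sca-1+ luminal and in basal against Sca-1- luminal libraries.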

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

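The tests of sources of RNA reported here were chosen after the results were seen, and the count over other splits of the luminal libraries was planned before.

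Sbp (chromosome 17, 23941996 to 23945607), which encodes a prostate secretory protein and a near copy of Sbpl, was left out of every comparison because it has no estimate in the 3 Sca-1- luminal libraries. It drew attention because it reached 18516 FPKM in Sca-1+ luminal replicate 2. The gene stood at 14365 FPKM in Sca-1+ luminal replicate 1 and 10.1 FPKM in replicate 3, at 1626 and 2958 FPKM in basal libraries and at 3066 and 6514 FPKM in stromal libraries. The files list 0 for it in all 3 Sca-1- luminal libraries, with the status HIDATA, which Cufflinks gives to a locus with too many fragments to estimate, so that 0 is not a level there.

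Sca-1+ luminal replicates 1 and 2 held genes of the stromal gate. For 207 genes high in stromal libraries and low in basal and Sca-1- luminal libraries, the median ratio to the stromal mean was 0.675 in replicate 1, 0.374 in replicate 2 and 0.057 in replicate 3. Expression by the Sca-1+ luminal cells of every library would not leave replicate 3 at a median of 0.081 of replicate 1 (quartiles 0.056 to 0.126), and a stromal library with a wrong label would not hold the 12 proximal luminal markers at a median of 16.8 times the stromal mean, as replicate 1 did. Stromal cells or their RNA in the gate may account for the pattern. In replicates 1 and 2, 0.836 or more of the 207 genes lay within 2-fold of the library's median ratio, although the share was also 0.797 in replicate 3. That window is wide, and the quartiles of the ratio in replicate 1 were 0.524 and 0.851. Col1a1 in replicate 1 stood above both stromal libraries, which dilution of RNA like that of the stromal libraries would not give. A made mixture of stromal replicate 1 and Sca-1+ luminal replicate 3 had a share of 1 within 2-fold of the median ratio. Stromal replicate 1 alone also had a share of 1 and is part of the stromal mean, so that outcome was set in advance. The same values shuffled over the genes gave 0.304, which shows only that the unshuffled values follow the stromal ones. Neither value separates stromal RNA in the gate from expression of these genes by the Sca-1+ cells of replicates 1 and 2. In the other direction, 38 genes were chosen as high in replicate 3 and low in Sca-1- luminal and stromal libraries. Their median ratio to replicate 3 was 0.159 in replicate 1 and 0.362 in replicate 2, with 0.947 of them within 2-fold of it in each. Mixing with stromal RNA would lower such genes by 1 ratio. The genes were chosen as high in replicate 3 itself, however, which favours ratios below 1. Whether the size of these ratios matches the stromal ratios of 0.675 and 0.374 was not tested. A gate high for CD24 would remove cells negative for CD24, and a real difference in Sca-1+ cells between these libraries was not tested.

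Transcripts of secretory proteins that were most abundant in Sca-1- luminal libraries appeared in all other libraries. Their median ratio to the Sca-1- luminal mean over 10 genes was 0.0189 and 0.0278 in basal, 0.0211 and 0.0434 in stromal, and 0.0888, 0.15 and 0.0848 in Sca-1+ luminal replicates 1, 2 and 3. For replicate 3, Sca-1- luminal cells or their RNA as the whole source is argued against by 3 genes below 0.1 of its median ratio, Msmb at 0.00637, Spink1 at 7.13e-05 and Sbpl at 6.95e-05. In the basal and stromal libraries and Sca-1+ luminal replicates 1 and 2 the number of such genes was 0, and Sca-1- luminal cells or their RNA stay open as the source there, with Spink1, the most abundant of the genes, at 0.0135 to 0.0337 of the Sca-1- luminal mean in basal and stromal libraries. The ratios were not uniform: the share within 2-fold of the median was 0.7 in both basal libraries and Sca-1+ luminal replicate 1, and 0.8 in both stromal libraries and Sca-1+ luminal replicate 2. In basal replicate 1 they ran from 0.00404 for Sbpl to 0.0504 for Defb50. Low expression by the sorted cells themselves was not tested, although the CD24 gates of basal and stromal cells would remove cells high for CD24 and the Sca-1 gate would remove cells without Sca-1.

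Seminal vesicle secretory genes differed in level between the Sca-1- luminal libraries. Over 5 genes, the median ratio to replicate 3 was 0.504 in replicate 1 and 0.0305 in replicate 2. RNA of 1 make-up entering these libraries in different amounts is consistent with 0.8 or more of the genes lying within 2-fold of the median ratio. RNA of the same make-up in the Sca-1+ luminal libraries is argued against, since at most 0.4 of the genes lay within 2-fold of the median there, with Svs2 at 0.446, 0.23 and 0.259 and Svs4 at 0.0196, 0.0197 and 0.0247 of Sca-1- luminal replicate 3. Seminal vesicle cells were not sorted in this study, and prostate lobes also express some of these genes, so expression that differs between animals was not tested.

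The real split of the 6 luminal libraries gave 4404 called genes, and the highest of the other 9 splits gave 2. With 10 splits in all, 1 of them as large as the real value, the splits are too few for a share under 0.05.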

How the results depend on the processing

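The fits with Sca-1+ luminal replicate 3 alone, with transcripts matched at both ends, with short transcripts, without genes listed at 0, and of stromal against basal and Sca-1- luminal libraries were chosen after the results were seen. All other alternatives were planned. Called genes between Sca-1+ and Sca-1- luminal libraries ranged from 2743 to 5239 with a library left out (4404 with all), basal against Sca-1- luminal from 3803 to 6465 (5771), basal against Sca-1+ luminal from 648 to 3608 (2475), stromal against epithelial from 1468 to 4892 (4280), and shared genes from 1857 to 3493 (3022). A lone library of a group was assumed to vary like the other groups. With transcripts matched at both ends, which leaves 5531 genes to test, the counts were 1878, 2458, 976, 1707 and 1283. With Sca-1+ luminal replicate 3 alone, which leaves fewer libraries, the luminal count was 2068 and the shared count 1520. A fit of the groups compared gave 1268 for basal against Sca-1+ luminal, and a minimum log2 change of 1 gave 1909 shared genes. With an estimated correlation 0 list tests were called by camera in limma, and 9 had an unadjusted p under 0.05. Pseudocount, filters, both scalings, library weights, short transcripts and genes listed at 0 kept each count within 1.5 times, as did basal and Sca-1- luminal libraries as the epithelium (4514). In those settings the luminal count was 3484 to 4502.

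Of 214 gene and comparison pairs followed, 210 kept direction and call with a pseudocount of 0.1 and 211 with median-of-ratios scaling. Under quantile normalization 2 pairs not called, B2m and Krt18, changed sign. Of 198 called pairs 6 lost their call there: Spink1, Pbsn, Wnt7b and Wnt4 between the luminal gates, Dcn in basal against Sca-1- luminal and Egfr in stromal libraries. The other called pairs kept direction and call. With a library left out 185 to 210 did, the fewest without basal replicate 1. With Sca-1+ luminal replicate 3 alone 130 of 155 pairs did, 18 were weaker, 4 stronger and 3 reversed. Directions turned for genes not called: Cd24a between the luminal gates with Sca-1+ luminal replicate 3 alone (0.66), Krt5 there without Sca-1- luminal replicate 3 (-0.22) or Sca-1+ luminal replicate 2 (-0.06; up to 0.90 with another library left out), Krt8 in basal against Sca-1- luminal without basal replicate 2 (-0.29) or Sca-1- luminal replicate 3 (-0.54; up to 0.98), Krt18 there without basal replicate 1 (0.11) or Sca-1- luminal replicate 2 (0.44; down to -0.60), Psca there without basal replicate 1 (0.048; down to -2.19), and in basal against Sca-1+ luminal with replicate 3 alone Krt15 (-0.47) and Dcn (1.23). The cause was not tested, beyond the loss of libraries that these settings entail. No paired analysis was possible because the labels carry no replicate numbers. Count-based tests were not run, since the files hold no counts. Depth of 20.3 to 27.2 M (mega) fragments limits genes near 1 FPKM most.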

Other observations

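No test was run for this part beyond the comparisons planned before, and the genes named here were chosen from the fixed lists after their values were seen.

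Of 10 polyamine genes tested, 3 were called between basal and Sca-1- luminal libraries and 7 were not. Odc1, ornithine decarboxylase, the enzyme that starts polyamine synthesis, stood at 367 ± 102 FPKM (SD, n = 2) in basal libraries, 46.6 ± 9.11 (SD, n = 3) in Sca-1- luminal and 53.1 ± 30.3 (SD, n = 3) in Sca-1+ luminal libraries. Smox, spermine oxidase, stood at 208 ± 70.7 FPKM (SD, n = 2) in basal and 22.3 ± 12.6 (SD, n = 3) in Sca-1- luminal libraries. Sat1, which acetylates spermidine and spermine, was highest in stromal libraries, at 1929 ± 85.3 FPKM (SD, n = 2), and lowest in Sca-1- luminal libraries, at 171 ± 36.7 (SD, n = 3). Odc1 and Smox had log2 changes of 2.94 and 3.29 in basal against Sca-1- luminal libraries, with limma Benjamini-Hochberg adjusted p of 0.000748 and 0.00133. Srm, spermidine synthase, was not called in that comparison, at 121 ± 14.5 FPKM (SD, n = 2) against 92.9 ± 18.2 (SD, n = 3).

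Several members of lists made to look for other cells were abundant in both luminal gates. The uroplakin genes Upk1a and Upk1b stood at 179 ± 22.7 and 86.2 ± 15 FPKM (SD, n = 3 each) in Sca-1- luminal libraries, 105.8 ± 45.3 and 87.2 ± 50.6 (SD, n = 3 each) in Sca-1+ luminal libraries and 6.57 ± 2.7 and 7.39 ± 2.37 (SD, n = 2 each) in basal libraries, whereas Upk2 was at 2.03 ± 0.376 FPKM (SD, n = 3) and Upk3a at 0.0932 ± 0.0807 (SD, n = 3) in Sca-1- luminal libraries. In Sca-1+ luminal replicates 1, 2 and 3, Upk2 stood at 1.94, 5.67 and 17.3 FPKM and Upk3a at 1.08, 1.17 and 1.21. Cd52, placed in the leukocyte list, stood at 318 ± 202 FPKM (SD, n = 3) in Sca-1- luminal, 232.5 ± 88.5 (SD, n = 3) in Sca-1+ luminal and 6.46 ± 3.27 (SD, n = 2) in basal libraries, while Tyrobp, an adaptor gene of myeloid cells, was at 3.18 ± 0.818 FPKM (SD, n = 3) in Sca-1- luminal libraries. Hemoglobin genes were highest in Sca-1- luminal replicate 3, with Hba-a1 at 439.5 FPKM against 107 and 72.1 in replicates 1 and 2. Within the immediate early list Ier3 stood at 3237 ± 236 FPKM (SD, n = 2) in basal and 192 ± 112 (SD, n = 3) in Sca-1- luminal libraries, and Fos at 129 ± 79.1 (SD, n = 2) and 579.5 ± 277 (SD, n = 3).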
